A study of Callithrix jacchus with 16 samples.

How the data were processed

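Spatial transcriptomes of 16 brain sections of the common marmoset were measured on 10x Visium slides, on which barcoded spots capture RNA from the tissue above them. The labels name 3 conditions, and these formed the groups: 11 sections with a T2 lesion from 5 animals, 3 healthy control sections from 1 animal, and 2 normal-appearing sections from 2 of the animals that also gave lesion sections. T2 refers to the magnetic resonance contrast on which the lesions were seen, and the animals with lesions had experimental autoimmune encephalomyelitis, an induced inflammatory demyelinating disease. Sections came from 3 library batches on 4 slides. The tissue names (fWM/aCC, OpT, pWM/pCC, oWM, tWM) are used as the labels give them.

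The deposited matrices hold raw UMI counts, 1 per gene and spot, for 20460 genes and 55029 spots, without normalization. Space Ranger 1.2.2 and Seurat 3.2.2 are listed by the authors among the processing tools. The genome build and gene coordinates are not given in the sources used here. The files give a symbol for 15691 genes. A symbol from the reference table of gene names was added for 952 more, and 3817 genes kept the Ensembl identifier. All 102 genes named in the text carry the file's own symbol. Genes of the major histocompatibility and immunoglobulin families resemble one another, so how their reads were divided among members is uncertain. Spot positions were not used, and images were not analysed here.

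Total depth per section ran from 4552684 to 24094827 UMIs over 2385 to 4348 spots. Spots with fewer than 500 UMIs were left out of the main comparisons (12398 spots, 1.5 to 43.9% of a section), which kept 42631. A neuronal score was taken per spot as log2 of 1 plus the UMIs of 15 neuronal genes per 10000 UMIs. Otsu's threshold over all sections, each weighted equally, fell at 5.22 (36.3 per 10000). The 13443 spots under it were called neuron-poor, as a stand-in for white matter, and the other 29188 neuron-rich. Within 0.5 of the threshold, on either side, lay 2956 spots. Among neuron-poor spots these were 78 of 194 and 93 of 219 in healthy_control replicates 1 and 2. In normal_appearing replicates 1 and 2 they were 42 of 91 and 65 of 360. Lesion sections ran from 39 of 2235 (T2_lesion replicate 8) to 162 of 792 (replicate 1). Sections with fewer than 50 spots of a class were left out of fits on that class, which removed healthy_control replicate 3 (11 neuron-poor spots). The healthy neuron-poor sum therefore rested on 413 spots of replicates 1 and 2.

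Counts were summed over spots, and the animal was the replicate, except that lesion against normal-appearing tissue and limma voom used section sums. The p-values of lesion against normal-appearing tissue therefore measure the spread between sections of an animal. The main test was the edgeR 4.0.16 quasi-likelihood test with TMM factors, filterByExpr on the design, and Benjamini-Hochberg adjusted p under 0.05, without a fold threshold. Lesion animals were compared with the healthy animal in neuron-poor and in neuron-rich spots. In both comparisons the single healthy animal was assumed to vary like the lesion animals. Lesion and normal-appearing sections were compared with the animal as a block, and normal-appearing with healthy tissue in a fit of all 3 groups. Within lesion sections, the 20% of neuron-poor spots with the highest share of UMIs in a myeloid list, or the lowest share in a myelin list, were compared with the other 80%, the animal being the block. The genes that chose the spots were left out of those tests. An interaction term compared the myelin-poor contrast, and separately the myeloid-rich contrast, between lesion and control sections. Shares of spots beyond the healthy 95th percentile of the myeloid score, or under the healthy 5th percentile of the myelin score, were computed after thinning each spot to 500 UMIs, with Wilson 95% intervals. Levels of gene lists are UMIs per 10000 with Poisson 95% intervals, which cover counting error only.

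All groups, spot classes, tests, gene lists and the naming rule were chosen before the data were examined, unless stated otherwise. Besides the neuronal, myeloid and myelin lists, 26 lists were tested: homeostatic microglia, lipid-associated myeloid, antigen presentation, complement, interferon response, T cell, B and plasma cell, granulocyte, reactive astrocyte, homeostatic astrocyte, mature oligodendrocyte (other than the myelin list), oligodendrocyte precursor and newly formed oligodendrocyte, cholesterol synthesis, lipid efflux, endothelial, endothelial activation, mural and fibroblast matrix, ependyma and choroid plexus, cell cycle, iron handling, senescence, hypoxia and glycolysis, immediate early and stress, erythrocyte, and glutamatergic and GABAergic gray matter. They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The naming rule took, among called genes with a mean log2 CPM (counts scaled to a common library size) of at least 5 and a symbol, the 12 highest and 8 lowest changes, and up to 4 members of each list with the smallest p. The text names part of these genes, and this part was picked after their values were seen. The few genes named outside the rule are marked where they stand. The values of 3 genes given by the rule are not reported here. A set of sex-linked genes for checking labels had 0 members in the files, so that check could not be made.

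Fold changes are on the log2 scale with standard errors. A gene with 0 counts in the healthy sum, or in either arm of a fit on single sections, was set against 3 counts over that sum, and a ratio to 1 to 3 counts is given with its 95% counting interval. Alternatives covered DESeq2 1.42.0, RLE factors, no filter on low counts, limma voom with tissue or batch as a covariate, other spot thresholds, thinning, and leaving out each animal or section. A minimum of 100 UMIs, a broad white-matter selection (100 UMIs and a neuronal threshold 1.5 higher), fits within a batch, spots matched on depth, fits without mitochondrial genes, lesion against healthy fits without 1 healthy section, and single normal-appearing sections against the healthy animal were added after the data were seen. Calculations ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. No pair of sections in a group held the same library (lowest chi-square per degree of freedom 29.6).

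The tests were tried on simulated data with 200 altered genes. With 5 animals against 1, edgeR recovered 37.3% of genes changed 4-fold and 90.9% of those changed 16-fold, with 2 false calls among 13303 unchanged genes. In the within-section design it recovered 80.6% (myeloid-rich) and 82.1% (myelin-poor) of genes changed 1.41-fold and 100% of those changed 2-fold, with 3 false calls among 11021 and 10 among 11468. A planted list reached p = 0.000229 in camera with an estimated correlation in the first design. Each gene was simulated independently, so the planted list held no correlation between genes. This value therefore does not show the power of that test on the real lists.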

Results

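Gene expression was measured with spatial barcodes in 16 brain sections from 6 common marmosets. The T2_lesion group held 11 sections from 5 animals with experimental autoimmune encephalomyelitis, an induced inflammatory disease that strips myelin from nerve fibres. The healthy_control group held 3 sections from 1 animal, and the normal_appearing group held 2 sections from 2 of the 5 diseased animals. Total depth in T2_lesion replicates 1 to 11 was 21375333, 20054858, 16915576, 13590068, 10261138, 17289539, 14821416, 18974931, 8125111, 13229807 and 6374119 UMIs. The healthy_control replicates held 17737742, 4552684 and 8815730 UMIs, and the normal_appearing replicates 24094827 and 7534931. Neuron-poor spots, used here in place of white matter, numbered 342 to 2235 per T2_lesion section. Healthy_control replicates 1 to 3 had 194, 219 and 11 of them, and normal_appearing replicates 1 and 2 had 91 and 360. Mitochondrial transcripts made up 26.6 and 19.4% of neuron-poor UMIs in the normal_appearing sections and 39.2 and 47.2% in healthy_control replicates 1 and 2. In T2_lesion sections they made up at least 11.0% and less than in normal_appearing replicate 1. Intervals on levels and shares cover counting error only.

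The first question was how neuron-poor spots, taken in place of white matter, differed between animals with lesions and a healthy animal. In neuron-poor spots, several transcripts of granulocytes and activated phagocytes were far more abundant in the 5 lesion animals. S100A8 (ENSCJAG00000005843), a calcium-binding protein of neutrophils and monocytes, reached 1809 ± 710 CPM (normalised counts scaled to a common library size; SD, n = 5) against 0 counts in the healthy animal, at least 563-fold higher (edgeR adjusted p = 0.0115). S100A12 was at least 126-fold higher. S100A9, the partner of S100A8, was 255-fold higher (counting interval 87.3 to 1240, 3 healthy counts). The matrix protease MMP9 was 644-fold higher (178 to 5320, 2 healthy counts). Of 8 granulocyte genes 4 rose, 5 when adjusted over the list alone. The list median was 7.57 on the log2 scale, or 5.83 with genes at 0 healthy counts set to the limit of 3 counts.

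Part of the genes of lipid-laden phagocytes rose in the same comparison. LGALS1 (ENSCJAG00000039253), a galactose-binding lectin, rose by 4.66 ± 0.46 on the log2 scale (SE, 5 against 1 animals), from 124 to 3130 ± 325 CPM. CTSB, a lysosomal protease, rose by 3.59 ± 0.47 and the integrin ITGAX by 2.71 ± 0.39. GPNMB and the chitinase CHIT1 had 1 healthy count each, with ratios of 144 (25.8 to 5670) and 1970 (354 to 77900). In the lipid-associated myeloid list 8 of 21 genes rose and 0 fell, 14 when adjusted over the list alone, with a median of 2.71 (2.04 at the limit). Of antigen presentation genes 7 of 15 rose, 11 when adjusted over the list alone, with a median of 2.81. CD74 (ENSCJAG00000038854), the invariant chain of class II molecules, rose by 5.13 ± 0.72, from 230 to 8077 ± 2571 CPM. The class II chain CAJA-DRA (ENSCJAG00000047567) rose by 4.50 ± 0.76 and the peptide transporter TAP1 by 2.81 ± 0.49. HLA-DPA1 had 2 healthy counts and a ratio of 125 (34.5 to 1030). Camera called all 3 of these lists with the preset correlation (adjusted p = 5.18e-13 for lipid-associated, 6.19e-13 for antigen presentation and 5.79e-13 for granulocyte genes), and none with an estimated correlation (adjusted p = 0.150, 0.131 and 0.129).

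Other called genes belonged to several lists. The general myeloid list, which was measured here but chose spots in later comparisons, had 3 of 19 genes up (5 when adjusted over the list alone), among them CYBB, a subunit of the phagocyte oxidase, at 3.18 ± 0.44 and the lipopolysaccharide receptor CD14 at 2.31 ± 0.42. The macrophage receptor VSIG4 had 1 healthy count and a ratio of 306 (54.9 to 12100). SLC11A1, a metal transporter of phagosomes, rose by 6.93 ± 0.50 and was the single call among 14 iron handling genes (3 over the list alone, median 0.47, or 0.26 at the limit). JCHAIN (ENSCJAG00000043740), which joins antibody subunits, rose by 6.12 ± 1.01, the single call among 10 B and plasma cell genes. Replication genes MCM2 and PCNA rose by 3.17 ± 0.40 and 2.42 ± 0.48, TYMS by 2.96 ± 0.62, and the mitotic kinase AURKB was at least 9.33-fold higher. In the cell cycle list 5 of 18 genes rose, 9 when adjusted over the list alone. Its median of 5.25 was 1.08 with the 9 genes at 0 healthy counts set to the limit. CDKN1A, an inhibitor of the cell cycle, rose by 3.26 ± 0.37, among 2 of 11 genes of the senescence list (4 over the list alone). ABCA1, a cholesterol exporter, rose by 3.28 ± 0.59, the single call among 12 lipid efflux genes.

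Astrocyte genes moved in different directions. TNC, an extracellular matrix protein, and the integrin ITGA5 rose by 4.50 ± 0.79 and 4.35 ± 0.91, and the hyaluronan receptor CD44 was at least 21.6-fold higher. MAOB fell by 2.85 on the log2 scale (SE 0.45). The reactive astrocyte list thus had 3 of 17 genes up and 1 down (7 and 1 over the list alone, median 2.36, or 2.09 at the limit). In the homeostatic astrocyte list 1 of 10 genes fell (4 over the list alone, median -0.97): the bicarbonate transporter SLC4A4, by 2.71 (SE 0.29). Steep falls among the genes given by the naming rule included IGSF1 (21.4 ± 12.5 against 1075 CPM), the Wnt modulator SFRP2 (ENSCJAG00000001920, 8.73 ± 1.99 against 287), the angiotensin precursor AGT (37.7 against 880, a log2 change of -4.55 ± 0.54) and the growth factor TGFB2 (47.3 ± 11.3 against 451). The proteoglycan BCAN fell by 2.87 (SE 0.54), 1 of 16 genes of oligodendrocyte precursors, and the vascular receptor FLT1 by 1.41 (SE 0.28), 1 of 15 endothelial genes. Of 14 GABAergic genes 2 fell (9 over the list alone, median -2.01), SLC32A1 and DLX1. Neuronal UMIs in the same spots were 9.36 ± 2.10 per 10000 in the lesion animals and 23.9 in the healthy animal. NEFL, which helped choose the spots, fell by 2.79.

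The remaining lists gave few calls. GBP1 rose, among 2 of 21 interferon response genes (median 0.89, or 0.56 at the limit, camera adjusted p = 0.140). EGR2 (ratio 38.6, 6.92 to 1520, 1 healthy count) and ATF3 (18.5, 5.12 to 153, 2 healthy counts) rose among 14 immediate early and stress genes, with 6 over the list alone. SERPING1, which restrains the complement cascade, rose by 1.46 ± 0.26, 1 of 10 complement genes. FN1 and LAMC1, extracellular matrix proteins, rose by 2.87 ± 0.49 and 1.91 ± 0.32, 2 of 22 mural and fibroblast genes (3 up and 4 down over the list alone, median 0.14, or -0.80 at the limit). CD9 rose by 2.04 ± 0.39, 1 of 22 other mature oligodendrocyte genes (median -0.07), and it also belongs to the lipid-associated list. No gene passed among 14 myelin (median -0.15), 9 homeostatic microglia (0.15, or -0.24 at the limit), 15 T cell (7.17, or -0.87 at the limit), 19 cholesterol synthesis (0.24), 10 endothelial activation (0.65, or -0.27 at the limit), 12 ependyma and choroid (0.77, or -0.26 at the limit), 13 hypoxia and glycolysis (0.47, or 0.37 at the limit) or 9 glutamatergic genes (-1.10). Erythrocyte genes were too sparse for a list test, at 0.54 ± 0.48 per 10000 UMIs against 0.43. The myelin result is limited by the healthy spots used. Myelin transcripts stood at 60.9 and 232.4 per 10000 in neuron-poor spots of healthy_control replicates 1 and 2. In spots under the UMI minimum they stood at 419.51 in the healthy animal and 268.64 ± 78.08 in lesion animals (SD, n = 5). The median of -0.15 therefore does not show like myelin levels in healthy and lesion white matter. Camera further called the myeloid, cell cycle, reactive astrocyte, homeostatic astrocyte, GABAergic, B and plasma cell, senescence, immediate early, complement and lipid efflux lists, and lost each with an estimated correlation (adjusted p from 0.129 for homeostatic astrocytes to 0.559 for complement).

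**Figure D1:**
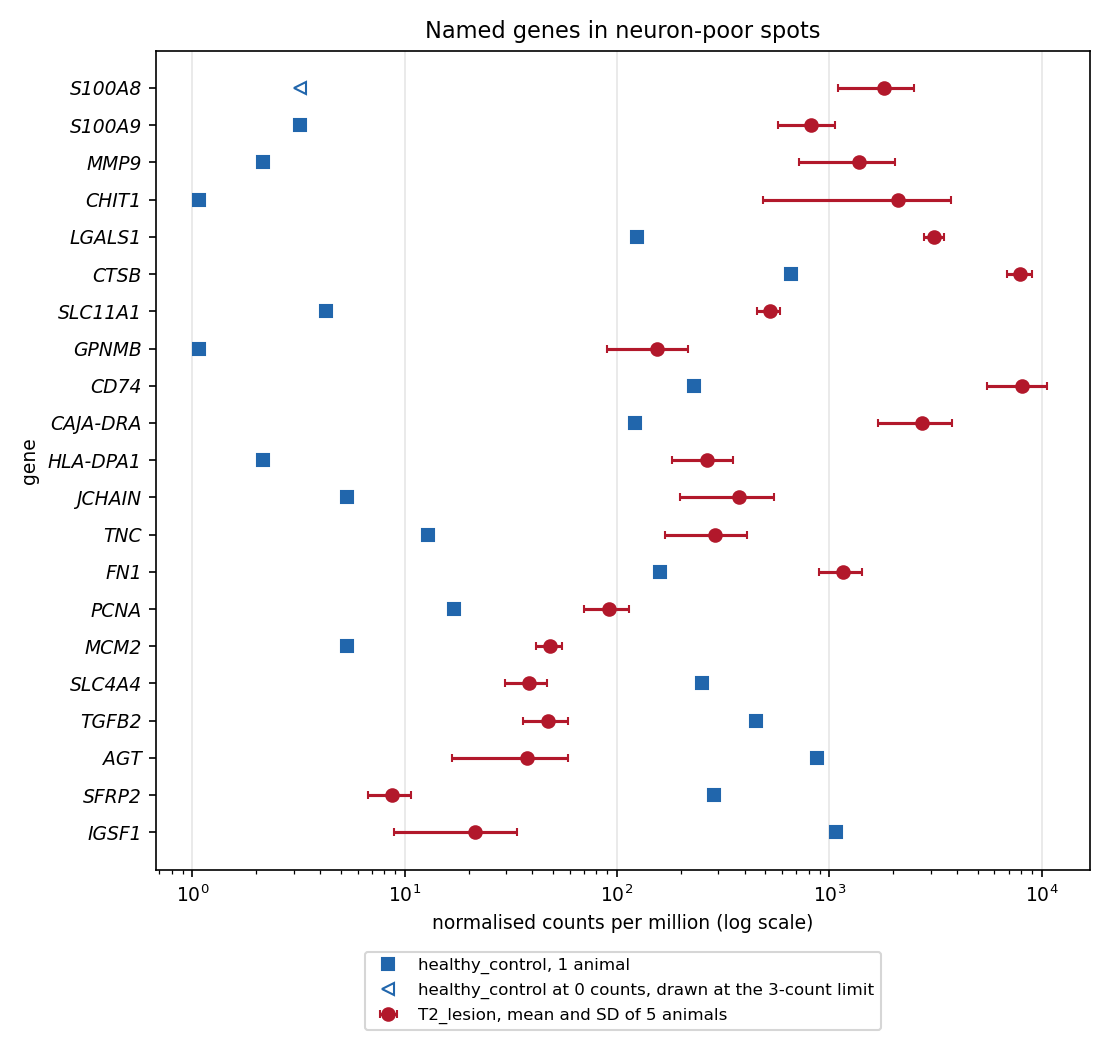
Normalised CPM (log scale) of 21 genes in neuron-poor spots, with the mean and SD of 5 T2_lesion animals as circles and the healthy animal as squares, or as an open triangle at the limit of 3 counts where it had 0. S100A8 stood at 1809 against 0 counts and IGSF1 at 21.4 against 1075.

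In this comparison edgeR called 627 of 13655 genes, 306 higher and 321 lower, and each of them differed from the healthy animal in the same direction in 5 of 5 animals. They were called on these same sums, all set against 1 healthy sum. The shared direction therefore follows largely from the selection and is not a replication. Changes are relative to an all-gene median of 0.25, which moved by between -0.26 (tissue as a covariate in limma voom) and 0.56 (without healthy_control replicate 1) in the other settings. The healthy side was 413 spots of 1 animal, so the animal could not be separated from the group, and its spread was assumed to be that of the lesion animals. Of the healthy spots, 78 of 194 (replicate 1) and 93 of 219 (replicate 2) lay within 0.5 of the neuron-poor threshold. In lesion sections this ran from 39 of 2235 to 162 of 792, so a larger part of the healthy side was borderline. DESeq2 called 1184 genes, and edgeR called 10 when all spots of the sections were used and 293 with a stricter neuron-poor threshold. Without 1 lesion animal the count was 216 (CJM10), 262 (CJH09), 362 (CJH11), 383 (CJP08) or 471 (CJM07). It was 1263 without healthy_control replicate 1 and 417 without replicate 2. Within batch B01 edgeR called 386 genes and within batch B03 1516. With genes at 0 healthy counts set to the limit of 3 counts, medians of the lipid-associated list were 1.55 and 3.69 in these batches, of antigen presentation 2.39 and 3.98, of granulocyte genes 6.35 and 6.28, and of reactive astrocyte genes 1.12 and 1.72. The homeostatic astrocyte medians were -1.20 and -1.34. The cell cycle median was 1.48 and 0.26 (10 of 14 genes at 0 healthy counts in B03), and -0.79 without healthy_control replicate 1. Of GABAergic genes 2 of 12 were lower in B01 and 0 of 11 in B03 (median -1.40 at the limit), and without healthy_control replicate 1 the median was -0.31 (-1.28 at the limit) with 0 of 14 lower. The myelin median turned from 0.48 in B01 to -1.43 in B03, where 5 of 13 genes were lower.

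In neuron-rich spots, taken as gray matter, the same animals were compared. CD74 stood at 1046 ± 856 CPM in the lesion animals and 25.2 in the healthy animal, a log2 difference of 5.38 ± 1.28 (edgeR adjusted p = 0.739). SLC11A1 differed by 5.38 ± 0.96, LGALS1 by 2.98 ± 0.68 and the adhesion molecule VCAM1 by 2.61 ± 0.57, each above the healthy animal in 5 of 5 animals and none past the threshold. Adjusted over the list alone, 10 of 15 antigen presentation genes (median 2.86), 8 of 17 reactive astrocyte genes (2.48), 4 of 7 granulocyte genes (5.39), 4 of 19 lipid-associated genes (1.25) and 4 of 10 complement genes (1.05) were higher. Camera called the antigen presentation list at an adjusted p of 3.49e-22, and the estimated correlation gave an adjusted p = 0.210. Interferon response genes had a median of 1.44 with 0 of 20 called, and 3 erythrocyte genes a median of 4.21 (2.28 at the limit, camera adjusted p = 0.270). EdgeR called 0 of 13940 genes (528 at an unadjusted p under 0.05), DESeq2 135 and limma voom with tissue as a covariate 122. Without CJP08 edgeR called 2.

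The next question was how lesions differed from normal-appearing tissue of the same animals, which rested on CJH11 and CJH09. In CJH09 the lesion sections were tWM and the normal-appearing section pWM/pCC, so lesion and brain region cannot be told apart there. In CJH11 the lesion sections were oWM and tWM and the normal-appearing section oWM. No gene passed. C1QA, a complement subunit made by microglia, differed by 1.82 ± 0.63 on the log2 scale (SE, 4 lesion and 2 normal-appearing sections), and the lysosomal lipase LIPA by 1.76 ± 0.57. EGR2 differed by 1.94 ± 0.42. The oligodendrocyte genes QDPR, TF and ANLN differed by -1.65 ± 0.57, -1.46 ± 0.59 and -1.27 ± 0.44 (edgeR adjusted p = 0.677 for each gene named here). With all spots of the sections the values of TF and ANLN turned to 0.04 and 0.44. Lipid-associated genes had a median of 1.36 (0 of 21 called), antigen presentation genes 1.45 (0 of 15, 1 over the list alone), myeloid genes 1.19 (0 of 19), myelin genes -0.95 (0 of 14) and other mature oligodendrocyte genes -0.81 (0 of 22). Camera called these 5 lists, at an adjusted p of 6.14e-09 for the lipid-associated list, and none kept its call with an estimated correlation (adjusted p = 0.372 for the first 3 and 0.386 for the others). The medians depended on which normal-appearing section was left out. Without replicate 2 and without replicate 1, lipid-associated medians at the limit of 3 counts were 3.24 and 0.50. Myeloid medians were 1.91 and 0.63, and other mature oligodendrocyte medians -2.13 and -0.04.

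The normal-appearing sections were unlike each other. Replicate 1 (CJH11, oWM) held 14.3 antigen presentation UMIs per 10000 in neuron-poor spots (Poisson 95% interval 11.9 to 17.0), near the healthy animal's 15.1. Replicate 2 (CJH09, pWM/pCC) held 174 (172 to 176), within the 143 to 267 of the lesion animals. Granulocyte genes stood at 0.22 and 43.4 per 10000 in the same sections, against 45.9 ± 12.2 (SD, n = 5) in lesion animals and 0.16 in the healthy animal. Myelin genes stood at 561 and 127 per 10000. EdgeR called 0 of 12444 genes (842 at an unadjusted p under 0.05) and DESeq2 2. Without normal_appearing replicate 2 edgeR called 293 genes, 175 higher and 118 lower. This fit set 2 lesion sections of CJH11 against 1 section of 89532 UMIs, assumed to vary like the others, in which 6139 of 13236 genes had 0 counts. With those at the limit of 3 counts the all-gene median was -1.30, the antigen presentation median 3.72 and the myelin median -2.20. Without replicate 1 edgeR called 0, and the 2 list medians were 0.39 and 0.20.

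**Figure D2:**
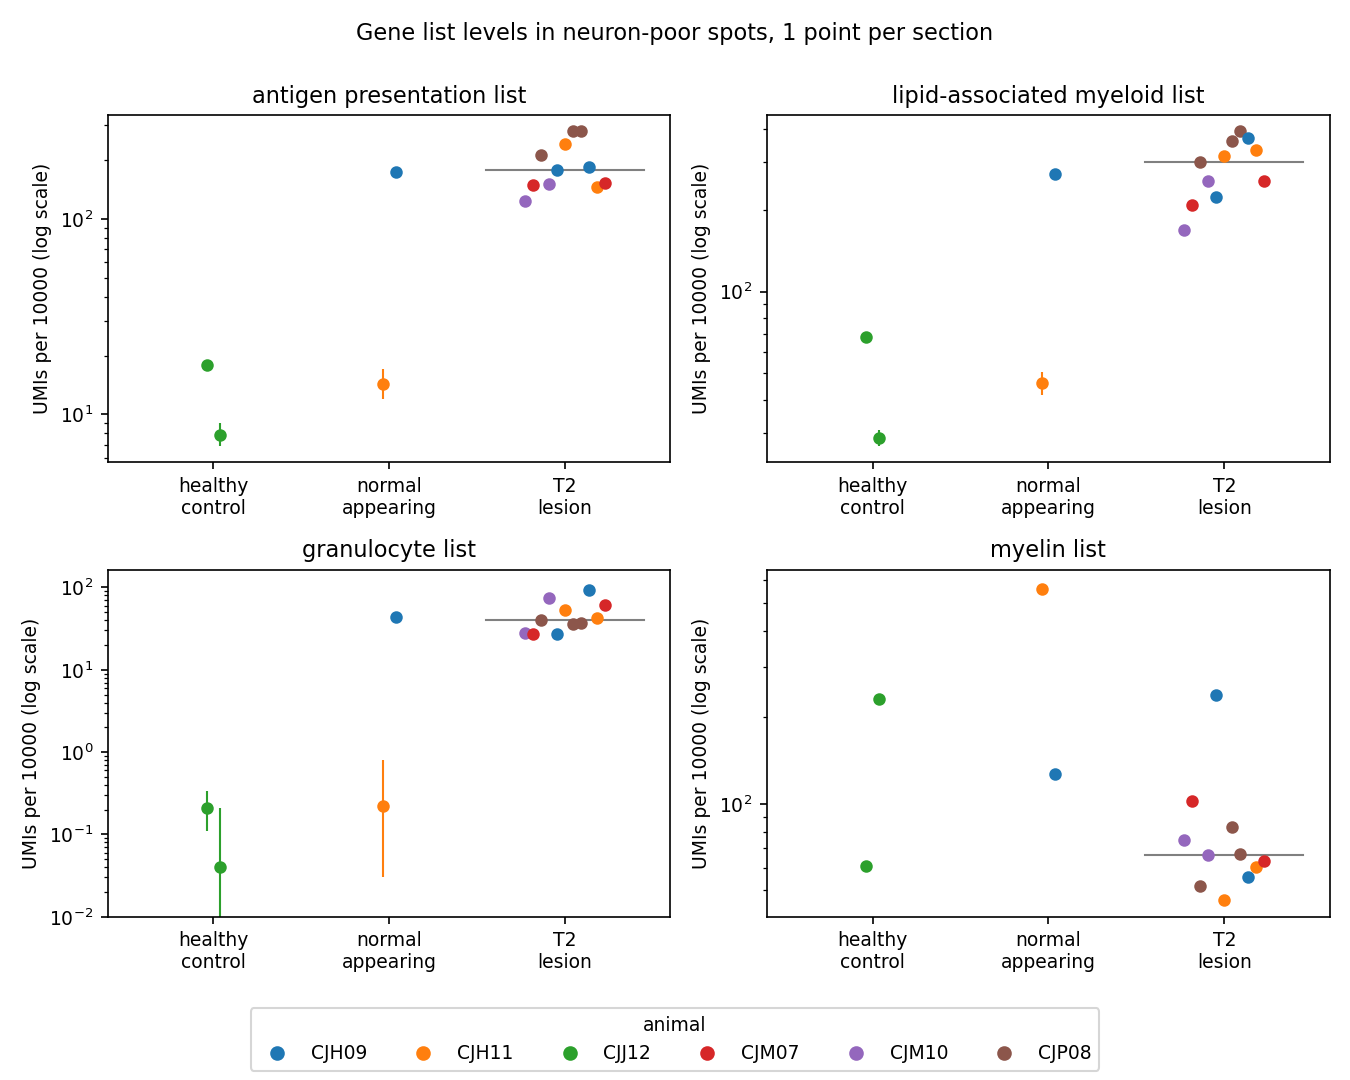
UMIs of 4 gene lists per 10000 UMIs (log scale) in the neuron-poor spots of each section with at least 50 of them, by group and colored by animal, with Poisson 95% intervals, and a gray line at the median of the T2_lesion sections. Antigen presentation genes of the normal_appearing sections stood at 14.3 and 174, and the interval of the lowest granulocyte point leaves the axis.

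Normal-appearing tissue was also compared with the healthy animal. The interneuron gene SST stood at 4.94 ± 4.80 CPM (SD, n = 2) against 85.3, and GAD1, an enzyme of GABA synthesis, differed by -2.06 ± 0.58 on the log2 scale. TNC differed by 3.31 ± 0.86 and SLC4A4 by -1.82 ± 0.48, and none of these passed (edgeR adjusted p = 0.432). Adjusted over the list alone, 4 of 13 GABAergic genes were lower (median -2.90) and 5 of 8 granulocyte genes higher (6.25, or 4.64 at the limit). Cell cycle genes had a median of 5.34 (0.53 at the limit) with 0 of 18 called. Camera called these 3 lists (adjusted p = 4.81e-08, 5.93e-05 and 3.55e-07), and an estimated correlation gave adjusted p = 0.340, 0.385 and 0.385. EdgeR called 0 of 13458 genes (1243 at an unadjusted p under 0.05), DESeq2 48 and limma voom 0. Without the CJH11 section edgeR called 5, and without the lesion sections of CJP08 it called 2. The antigen presentation median of 1.59 at the limit was 1.95 without CJH11 and -0.25 without CJH09, each fit resting on 1 normal-appearing section assumed to vary like the other groups. The all-gene medians at the limit were -0.17 without CJH11 and 0.82 without CJH09. Without CJH09, 6010 of 13107 genes had 0 counts in the normal-appearing section, so list medians of that fit depend on the limit. The GABAergic median at the limit was -2.42 without CJH11 and 0.31 without CJH09. These genes stood at 2.68 per 10000 in the CJH11 section (Poisson 95% interval 1.72 to 3.99), 1.16 (0.99 to 1.33) in the CJH09 section and 3.76 in the healthy animal, so the lower level rested on CJH09. Granulocyte genes stood at 0.22 (0.03 to 0.81) in the CJH11 section, 43.4 in the CJH09 section and 0.16 in the healthy animal. Their higher level rested on CJH09 as well.

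Within lesion sections, spots rich in myeloid transcripts were compared with other neuron-poor spots of the same sections, to see what accompanied myeloid cells. The 19 myeloid genes that chose the spots were not tested, and other genes of the same cells follow by construction. Part of the lymphocyte genes were higher there. GIMAP4, a small GTPase of lymphocytes, rose by 0.92 ± 0.07 on the log2 scale (SE, 5 animals), and the T cell genes CD2 and CD3G by 0.90 ± 0.09 and 0.77 ± 0.17. Of 12 T cell genes 6 rose (7 over the list alone). JCHAIN rose by 1.13 ± 0.18, from 294 ± 176 to 597 ± 216 CPM, and the B cell coactivator POU2AF1 by 1.19 ± 0.16, with 5 of 10 B and plasma cell genes up. Antigen presentation genes rose in 11 of 15 cases (11 over the list alone, median 0.45), including HLA-DPA1 at 0.75 ± 0.11, CAJA-DRA at 0.64 ± 0.10 and HLA-E at 0.62 ± 0.09. Camera called the 3 lists (adjusted p = 4.70e-06, 1.39e-07 and 3.31e-10), and an estimated correlation gave adjusted p = 0.0881, 0.0881 and 0.117.

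Some phagocyte genes outside the defining list were also higher in these spots. The lipid carrier APOE rose by 0.55 ± 0.09, the lipid receptor TREM2 by 0.35 ± 0.08, and 7 of 20 lipid-associated genes did so (8 over the list alone, median 0.24). The engulfment receptor MERTK, the mannose receptor MRC1 and the purine receptor P2RY13 rose by 0.77 ± 0.08, 0.77 ± 0.14 and 0.65 ± 0.08. Homeostatic microglia genes rose in 4 of 7 cases (median 0.39), lipid efflux genes such as NR1H3 in 3 of 12 (4 over the list alone), granulocyte genes such as CSF3R in 2 of 8 (3 over the list alone), interferon genes in 6 of 21, and the chemokine CXCL12 was 1 of 2 endothelial activation genes up. Camera called the first 5 of these lists, and none kept its call with an estimated correlation (adjusted p = 0.454, 0.117, 0.158, 0.386 and 0.447).

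Oligodendrocyte, astrocyte and choroid plexus genes were lower in myeloid-rich spots. Spots were ranked by the myeloid share of UMIs, so spots made mostly of other cells land among the other spots by construction. How much of the lower levels comes from that was not tested. Of 21 other mature oligodendrocyte genes 18 fell (median -0.68), among them the iron carrier TF by 0.92 (SE 0.11) and CARNS1 by 0.77 (SE 0.09). Of 13 myelin genes 12 fell (median -0.68), including MAG by 0.79 and MOG by 0.84, and 9 of 15 precursor and newly formed oligodendrocyte genes (10 over the list alone), including SOX10 by 0.53 and BCAS1 by 0.58. The tubulin TUBB4A and the transporter SLC5A11 (ENSCJAG00000020690) fell by 0.96 (SE 0.14) and 1.04 (SE 0.11). The water channel AQP4 and SLC4A4 fell by 0.73 and 0.72, 2 of 6 homeostatic astrocyte genes that did so among 10. Reactive astrocyte genes went both ways, with 2 of 17 up and 7 down, GFAP by 0.43 and CRYAB by 0.53. All 10 ependyma and choroid genes fell (median -1.52), TTR (ENSCJAG00000043128), the choroid plexus carrier of thyroid hormone, from 952 ± 923 to 68.3 ± 72.3 CPM, PRLR by 3.14 and KCNJ13 by 2.83. An estimated correlation gave adjusted p = 0.117 for other mature oligodendrocyte, 0.210 for myelin, 0.117 for precursor, 0.131 for homeostatic astrocyte and 0.0613 for ependyma genes, all 5 called by camera with the preset one. Calls in the other lists were few: DUSP1 was 1 of 4 immediate early genes down, FEZF2 1 of 3 glutamatergic genes down beside 1 up, MSMO1 1 of 2 cholesterol synthesis genes down, and 0 of 14 cell cycle genes passed.

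The test between these spots called 2096 of 11494 genes, 904 higher and 1192 lower, of which 823 and 1059 had the same direction in 5 of 5 animals. The animal was a block in edgeR. Without that block 0 genes passed (921 at an unadjusted p under 0.05), DESeq2 with the block called 1554 genes and limma voom with batch as a covariate 773. Without CJH09 edgeR called 1268. Myeloid-rich spots had the higher median depth in 10 of 11 sections (2086 against 2516 UMIs in T2_lesion replicate 4, the exception), and with other spots matched on depth the medians were 0.40 for antigen presentation, -0.46 for other mature oligodendrocyte and -1.33 for ependyma genes.

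Spots poor in myelin transcripts were compared in the same way, to see what accompanied myelin loss. Myelin genes were not tested, and other oligodendrocyte genes follow by construction. Of 21 other mature oligodendrocyte genes 19 fell (median -1.30): ST18 by 2.02 (SE 0.14), APLP1 by 1.56 (SE 0.15), GAL3ST1, which makes the myelin lipid sulfatide, by 1.37 (SE 0.11), and TF by 1.77 (SE 0.20). SLC5A11 fell from 102 ± 51.6 to 20.8 ± 8.06 CPM (SD, n = 5), TUBB4A by 2.04 and FOLH1 by 2.00. The lineage factors SOX10 and NKX2-2 fell by 1.12 and 0.82, among 9 of 15 precursor and newly formed oligodendrocyte genes (10 over the list alone). An estimated correlation gave adjusted p = 0.0720 for each of these lists, both called by camera.

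Cell cycle genes and part of the immune genes were higher in myelin-poor spots. Of 16 cell cycle genes 10 rose (12 over the list alone, median 0.60), including CCNB1 by 0.70 ± 0.17, TYMS by 0.58 ± 0.08, MCM2 by 0.57 ± 0.10 and PCNA by 0.51 ± 0.08. PTTG1 rose by 0.81 ± 0.09. S100A8, S100A9 and S100A12 rose by 0.88 ± 0.10, 0.81 ± 0.10 and 0.66 ± 0.10, 3 of 8 granulocyte genes (4 over the list alone). Of 19 myeloid genes 8 rose (9 up and 1 down over the list alone), such as CD14 by 0.59 ± 0.10 and AIF1 by 0.33 ± 0.07, and 10 of 15 antigen presentation genes (11 up and 1 down over the list alone), such as PSMB9 by 0.61 ± 0.10, HLA-E by 0.50 ± 0.09 and HLA-DPA1 by 0.50 ± 0.08. The B cell genes POU2AF1 and DERL3 rose by 1.64 ± 0.32 and 0.84 ± 0.14, among 4 of 10 (7 over the list alone), and CD28 was 1 of the 4 T cell genes up among 13. Camera called the cell cycle list (adjusted p = 1.56e-07) and the other 5. With an estimated correlation each had an adjusted p = 0.193.

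Further genes of the myelin-poor comparison included matrix and astrocyte genes, among others. None of the tested genes of the endothelial list passed. The matrix genes DCN and MMP1 rose by 1.14 ± 0.21 and 1.01 ± 0.15 and FN1 by 0.49 ± 0.12. The hemoglobin chain HBB rose by 1.54 ± 0.17 but in 4 of 5 animals. MRC1 and CXCL12 rose by 0.82 ± 0.09 and 0.81 ± 0.15. LGALS1 and CTSB rose by 0.38 ± 0.10 and 0.48 ± 0.13, among 5 of 21 lipid-associated genes (7 over the list alone). The microglial factor SALL1 and the cholesterol transporter NPC1 fell by 0.61 and 0.48. GFAP, AQP4 and the glutamate transporter SLC1A2 fell by 0.61, 0.39 and 1.01, while ITGA5 rose by 0.56 ± 0.11. Reactive astrocyte genes had 3 of 17 up and 1 down, and homeostatic astrocyte genes 3 of 10 down (4 over the list alone). CXCL9 rose by 1.57 ± 0.35 and IFIT2 fell by 1.34, among 21 interferon response genes with 6 up and 1 down. Ependyma genes had 0 of 10 called (median 0.20).

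**Figure D3:**
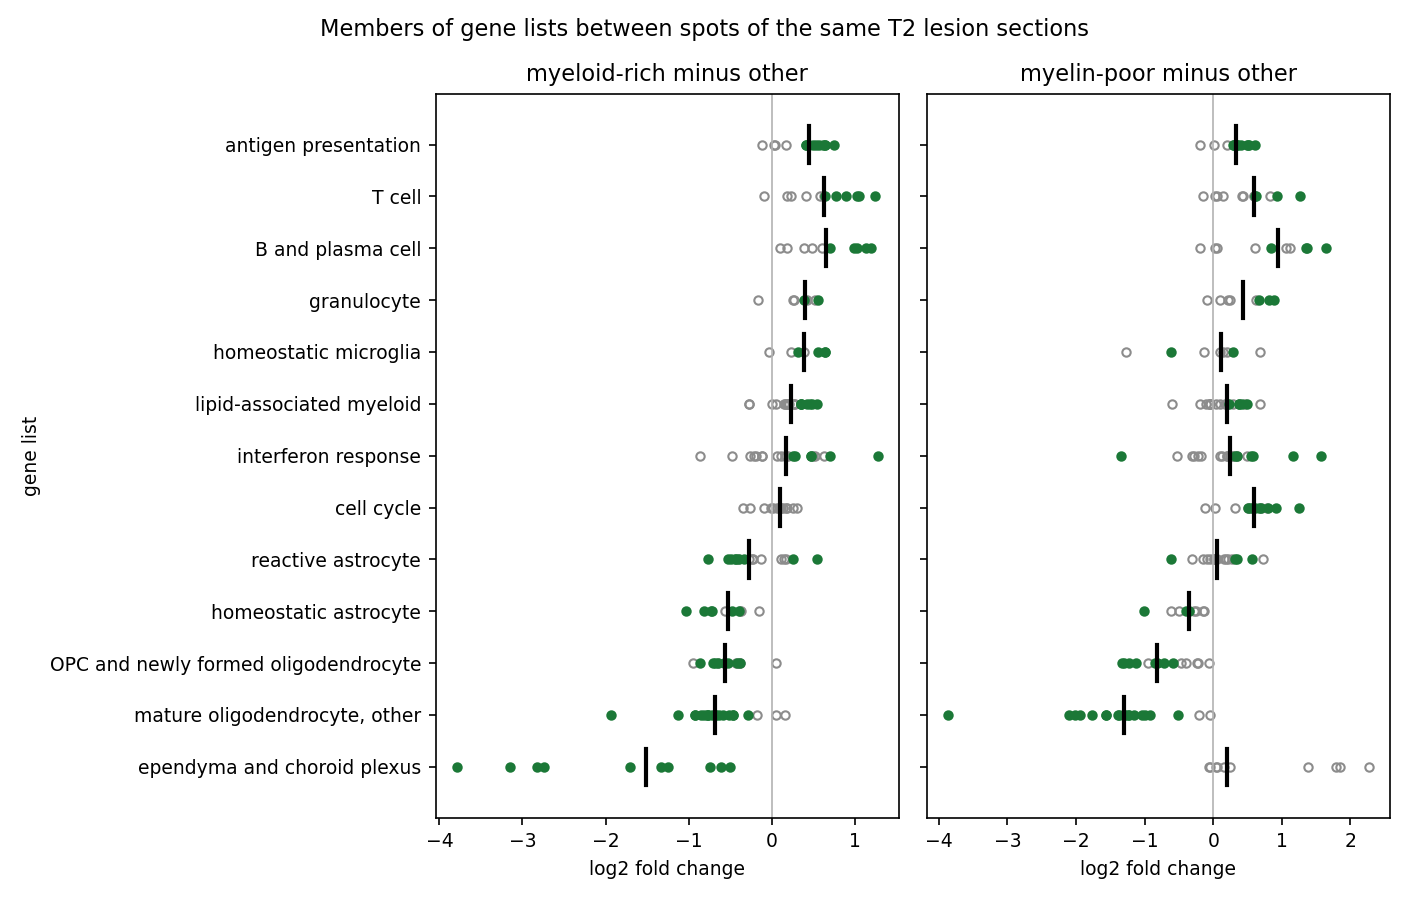
Log2 fold changes of the members of 13 gene lists between myeloid-rich and other spots and between myelin-poor and other spots of the T2_lesion sections, with called genes filled, others open, and black bars at list medians. Cell cycle medians were 0.09 and 0.60, and ependyma medians -1.52 and 0.20.

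The test between myelin-poor and other spots called 1960 of 11917 genes, 891 higher and 1069 lower, of which 819 and 1001 had the same direction in 5 of 5 animals. Without the animal as a block edgeR called 0 (1159 at an unadjusted p under 0.05), DESeq2 with the block called 1605 and limma voom with batch as a covariate 906. Without CJM07 edgeR called 1254. Myelin-poor spots had the higher median depth in 11 of 11 sections (6873 against 1721 UMIs in T2_lesion replicate 1), and with other spots matched on depth edgeR called 1249. With matched depth, cell cycle genes had a median of 0.51 (8 of 13 higher) and 17 of 20 other mature oligodendrocyte genes were lower. Of myeloid-rich spots, 23.4% in CJH11 to 47.1% in CJM07 were also myelin-poor, where 20% would be if the classes were independent.

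Whether the myelin-poor contrast differed between lesion and control sections was tested with an interaction in edgeR, the controls being the healthy and normal-appearing sections. Of 11053 genes 1 passed: CEMIP (ENSCJAG00000007708), which takes part in breaking down hyaluronan and was named after its values were seen (709 genes at an unadjusted p under 0.05). Its contrast was lower in lesion sections by 2.29 on the log2 scale (adjusted p = 0.00108). DESeq2 called 1 gene, and edgeR called 0 without the healthy animal, 4 without the normal-appearing section of CJH09, CEMIP not among them, and 11 without CJM10. Complement genes had a median of -0.92 with 0 of 9 called (2 lower over the list alone, camera adjusted p = 5.94e-08), and an adjusted p = 0.0608 with an estimated correlation.

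The share of neuron-poor spots above the healthy 95th percentile of myeloid transcripts was 8.37 ± 3.73% in lesion animals (SD, n = 5), 4.64% in the healthy animal and 2.76 ± 0.80% in normal-appearing tissue (n = 2). It was highest in T2_lesion replicate 8, at 17.99% (Wilson 95% interval 16.45 to 19.63), and lowest in replicate 1, at 3.28% (2.25 to 4.77). Healthy_control replicate 1 had 9.28% (5.95 to 14.19) and replicate 2 had 0 of 219 spots (upper limit 1.72%). An exact permutation test of 5 against 1 animals cannot give a p below 0.167. Without healthy_control replicate 1 the lesion mean was 38.72%, and without replicate 2 it was 4.15%. The normal-appearing mean lay above the healthy share without healthy_control replicate 1 (16.06 against 13.86%) and with the broad selection (8.48 against 4.97%). It lay below the healthy share in the other settings. The matching share for low myelin could not be read, since the healthy 5th percentile was 0 after thinning to 500 UMIs.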

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

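Chosen only after the results were seen were the tests of the UMI minimum on the genes higher in lesion animals, of list medians within batches, of sex or age, of normal_appearing replicate 2, and of fewer oligodendrocytes in myelin-poor spots. The other tests in this part were chosen before their results were seen.

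Neuron-poor spots of the lesion animals and the healthy animal differed in 627 genes, and 3 technical explanations and the sex or age of the animals were tested. If the minimum of 500 UMIs had made the difference by removing healthy white matter, spots under the minimum should not show it. Of the higher genes, 97.7% were also higher in lesion spots under the minimum (298 genes, against 58.0% of all tested genes), and of the lower genes 84.3% were also lower there (287 genes). Of 609 called genes, 98.5% had the same sign within both batches that hold healthy sections (66.8% among all genes). They were called on these same sections, a single one of its own tissue per batch. Selection therefore raises this share, and it cannot decide on library batch. Batch as the whole cause would leave no difference within a batch. At the limit of 3 counts, antigen presentation medians were 2.39 in B01 and 3.98 in B03, and granulocyte medians 6.35 and 6.28. This argues against batch as the whole cause for these lists. The myelin median turned from 0.48 to -1.43. Sex or age as the whole cause was argued against by CJH11, the lesion animal of the healthy animal's sex and nearly its age (1516 and 1592 days). It lay nearer the other lesion animals than the healthy animal in 98.3% of the 362 genes called without it (81.5% of all 12862 tested), where sex or age as the cause would set it near the healthy animal. RNA from neuron-rich tissue cannot be told apart for the lower genes, since 62.0% of them stood higher in neuron-rich healthy spots, near the 56.4% of all tested genes, and the animal itself and RNA quality stay open as well because 1 animal gave all healthy sections.

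Normal_appearing replicate 2 held antigen presentation transcripts near the lesion level (174 per 10000). Brain region as the whole cause was argued against by the healthy section with the same tissue name, at 7.89 per 10000. The same section was the single healthy one of that batch with enough spots, so its value of 7.89 also argues against library batch as the whole cause. It lay on another slide, and the slide stays open. A swap with a lesion section would leave a low section among the lesions, and the lowest of these stood at 123.88. A single wrong label, a lesion inside the section and a diffuse change of tissue outside lesions in this animal stay open, and spot positions were not used to part them.

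Cell cycle genes were higher in myelin-poor spots (median 0.60). With other spots matched on depth the median was 0.51, and leaving out 1 animal at a time gave 0.51 at the lowest, which argues against depth and against 1 animal as the whole cause. Fewer oligodendrocytes would raise the transcripts of all other cells alike, but the homeostatic astrocyte median was -0.36 (3 of 10 lower, 0 higher) and the endothelial median 0.11 (0 of 10 called), which argues against this as the whole cause. Myeloid and antigen presentation medians of 0.32 and 0.34 go with it, so a part in the rise stays open. More dividing cells in myelin-poor spots is a candidate explanation that stays a hypothesis, since it was found and tested on the same data, and which cells divide was not tested.

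For the within-section comparisons, other splits of the sums into the 2 classes were tried. Each animal gave 1 sum of each class, and only 16 splits keep that pairing, too few for a share under 5%. For myeloid-rich spots 1 of the 16, the real one, gave as many as 2096 genes, and the highest other gave 0. For myelin-poor spots 1 of the 16, again the real one, gave as many as 1960 genes, and the highest other gave 1. Among 60 splits that also included unpaired ones, which put both sums of an animal in 1 class, the highest other gave 1943 and 658. In each of these, 3 animals kept their real classes, so these splits hold part of the real contrast and cannot stand for chance. Other unpaired splits that kept 3 animals gave at most 14 for myeloid-rich and 0 for myelin-poor spots. For the interaction of the myelin-poor contrast with lesion or control sections, 27 of 56 splits gave at least as many as the real 1 gene and the highest, which is among the 16 named next, gave 25. CJH09 and CJH11 each gave a lesion and a normal-appearing unit, and among the 16 splits that keep these apart 6 did so, so chance cannot be excluded. For the interaction of the myeloid-rich contrast, 21 of 56 splits, and 6 of the same 16, gave at least as many as the real 5 genes, so chance cannot be excluded there either. The highest of the 56 gave 331 and the highest of the 16 gave 65, many times the real count, and what those units have in common was not tested.

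Among lesion animals, 1 animal stood far from the other 4 in 4 of 34 sets of values, where chance gives about 1 in 20. Homeostatic astrocyte genes in neuron-poor spots stood at 4.7 per 10000 in CJM10 (next 6.34). Cholesterol synthesis genes stood at 12.69 in CJM07 (next 7.24). Hypoxia and glycolysis genes stood at 16.33 in CJP08 (next 12.72). The median depth of neuron-poor spots, averaged over the sections of an animal, was 13870.5 UMIs in CJH11 (next 4930.25), from 21369 in T2_lesion replicate 6 and 6372 in replicate 10.

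Interaction tests called genes for a contrast that differed between lesion and control sections, in numbers that chance can give (see the splits above). For myelin-poor spots edgeR called CEMIP at -2.29 on the log2 scale (edgeR adjusted p = 0.00108). For myeloid-rich spots edgeR called 5 genes: ENSCJAG00000021091 at -3.72, SFRP2 at 3.80, OLR1 at -1.87, IGFBP3 at -1.29 and IGFBP5 at 1.29. These genes were named after their values were seen.

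In spots under the UMI minimum, which the main comparisons left out, antigen presentation transcripts stood at 75.05 ± 38.9 per 10000 in the lesion animals (SD, n = 5) and 5.34 in the healthy animal. Granulocyte transcripts stood at 13.1 ± 10.2 and 0.12.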

How the results depend on the processing

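Chosen after the data were seen were the settings with 100 UMIs, the broad white-matter selection, single batches, mitochondrial genes left out, matched depth, single healthy sections left out of lesion against healthy tissue, and single normal-appearing sections against healthy tissue. For lesion against healthy neuron-poor spots (627 genes), counts were 1184 with DESeq2, 10 with all spots, 293 with a threshold 0.5 lower, 332 with the broad selection, 386 within batch B01 and 1516 within B03, 216 to 471 without 1 lesion animal, and 1263 and 417 without healthy_control replicate 1 and 2. Of the 21 settings 9 stayed within 1.5 times, that without CJM07 (471) among them. For neuron-rich spots (0) they were 135 with DESeq2, 122 with limma voom on section sums, and 0 to 2 without 1 animal. For lesion against normal-appearing tissue (0) they were 2 with DESeq2 and 0 to 293 without 1 section. For normal-appearing against healthy tissue (0) they were 48 with DESeq2 and 0 to 5 without 1 animal. For myeloid-rich spots (2096) they were 773 with limma voom and batch, 1395 with the highest 10%, 1362 with the thinned score, 0 without the animal as block, and 1268 to 2407 without 1 animal. For myelin-poor spots (1960) they were 906 with limma voom and batch, 3106 with the section as block, 0 without the animal as block, 1249 with matched depth, and 1254 to 1564 without 1 animal. For the interaction (1) they were 31 without the filter on low counts, 5 for myeloid-rich spots, and 0 to 11 without 1 animal. Without the block, the spread between animals enters the error by construction. The cause of the other shifts was not tested. The mean lesion share of myeloid-high spots (8.37%) was 2.25% with the 99th percentile, 4.30% with the lower threshold, 20.17% with the broad selection, and 38.72% and 4.15% without healthy_control replicate 1 and 2. The mean lesion share of myelin-low spots, 0 by construction, was 4.58% unthinned, 9.02% with the lower threshold, 5.04% with the broad selection and 20.88% without healthy_control replicate 1. The healthy shares in these settings were 4.89, 4.7, 4.99 and 13.46%. The lesion share was thus lower unthinned and nearly equal with the broad selection. Camera called 90 of 213 list tests, 0 with an estimated correlation and fry 32. Among the named genes, TF and ANLN between lesion and normal-appearing tissue reversed with all spots, from -1.46 to 0.04 and from -1.27 to 0.44. All other named genes kept their direction in the settings run. Past the threshold stayed 752 of 945 values of the 45 genes named for lesion against healthy neuron-poor spots, 524 of 578 of the 34 named for myeloid-rich spots and 606 of 693 of the 41 named for myelin-poor spots. With 5 animals against 1, simulated 2-fold changes were recovered in 3.0% of genes, so changes of that size were mostly out of reach.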

Other observations

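No test was run on the values in this part, and all but those of CJH11 oWM sections were chosen after the results were seen. CJH11 gave a lesion section and a normal-appearing section with the same tissue name (oWM). In neuron-poor spots, lipid-associated myeloid transcripts stood at 317 per 10000 UMIs in the lesion section (T2_lesion replicate 6) and 46.0 in normal_appearing replicate 1. Antigen presentation transcripts stood at 241 and 14.3, and granulocyte transcripts at 52.9 and 0.22. Myelin transcripts stood at 46.3 and 561, other mature oligodendrocyte transcripts at 44.2 and 163, and homeostatic astrocyte transcripts at 4.81 and 21.2. Iron handling transcripts stood at 149 and 68.1, and cell cycle transcripts at 6.32 and 13.4. The normal-appearing value rests on 91 spots and 89532 UMIs.

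B and plasma cell transcripts in neuron-poor spots stood at 41.4 per 10000 (Poisson 95% interval 41.1 to 41.7) in T2_lesion replicate 8 (CJP08, oWM), and between 3.21 and 13.04 in the other 10 lesion sections. Ependyma and choroid plexus transcripts ranged from 1.18 in T2_lesion replicate 6 (CJH11, oWM) to 31.7 in replicate 10 (CJH11, tWM), and reached 33.5 in normal_appearing replicate 2. Granulocyte transcripts were highest in T2_lesion replicate 9 (CJH09, tWM), at 91.9, against 27.3 in replicate 5 from the same animal and tissue name. In spots under the UMI minimum, reactive astrocyte transcripts stood at 248 ± 69.7 per 10000 in the lesion animals (SD, n = 5) and 74.1 in the healthy animal, lipid-associated transcripts at 103 ± 51.8 and 27.3, and myelin transcripts at 269 ± 78.1 and 420.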
